A study of Homo sapiens with 29 samples.

How the data were processed

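Cells from primary human breast tumours were sorted by flow cytometry on the antigens CD44 and CD24 after gating on lineage antigens and viability, per the labels' design text, and total RNA was extracted with Trizol, biotin labelled by the Affymetrix procedure and hybridised to arrays, per the labels' protocols. The 29 arrays comprised 14 of CD44+/CD24- cells and 15 of the other sorted cells, and groups and replicate numbers were taken from the sample titles. The values deposited by the authors are intensities per probe set on a linear scale. How the authors summarised probes, scaled arrays and set the lowest value is not given in the sources used here. That lowest value, 1.98, was shared by all arrays, so values at it have no order. No 2 arrays held identical values.

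The table held 54675 probe sets, of which 62 were controls. The platform annotation, which dates from 2016, gave 41091 probe sets 1 gene symbol, 1801 several and 11721 none. Symbols were updated by gene ID for 41037 probe sets and kept as in the annotation for 54. Probe sets with several or no symbols were left out, as were XIST and Y-linked genes. For each gene the probe set with the highest mean over the 29 arrays was used, which left 19740 genes, 10511 of them with several probe sets. No coordinates are given, since no genome build was named for the arrays.

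Values were analysed as log2(intensity + 16), so differences understate the change of dim genes. The design rule kept the values as deposited if array medians on the log2 scale lay within 0.5 of each other. Their range was 0.206 on log2(intensity + 16), the scale of the test, and the values were kept as deposited. On plain log2 the range was 0.574, which would have called for quantile normalization, and the rule did not say which scale it meant. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates) with Benjamini-Hochberg adjustment over all genes, at an adjusted p under 0.05. Differences are CD44+/CD24- minus non-CD44+/CD24-. On simulated data with 14 against 15 arrays and 19740 genes, the test recovered 87% of 100 genes changed by 1 on the log2 scale and 99% of 100 changed by 2. Of its 202 calls 16 were false (7.92%). The changed genes were picked at random from all genes, most of them dim, and noise was independent between genes. Recovery can be lower for more variable genes such as LUM (SE 0.73), so it does not measure power for the genes that did not pass.

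Before the data were examined, 35 gene lists were written, covering the sort antigens, the gated lineage antigens, cell types, epithelial and mesenchymal genes, stress and pathways. The 34 with at least 5 measured members were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Genes are named by a rule set at the same time: CD44 and CD24, the 10 largest differences each way among genes that passed, up to 4 members with the smallest p-values per list, and all lineage antigens. Genes named outside it were chosen after their values were seen. These are S100A8, S100A9 and HBB in the report, the genes in the opening paragraphs of the other observations, and there also the 5 most abundant fibroblast genes. Means per array were compared by permutation tests with 100000 resamples, or by exact enumeration within the array sets.

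The arrays split into 19 with at most 6.01% of probe sets at the lowest value (9 CD44+/CD24-, 10 other) and 10 with at least 6.43% (5 and 5). This technical split was found after seeing the data and used as a block and for values within each set. The alternatives planned before the data were examined were quantile normalization, centring on array medians, leaving out the lowest 40% of genes, pseudocounts of 1 and 64, other rules for the probe set of a gene, eBayes with trend and robust fitting, array weights, the replicate number as a fixed or random block, the 3-prime to 5-prime ratio as a covariate, and leaving out each array in turn.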

Results

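RNA was profiled on 29 expression arrays, each hybridised with RNA from cells of a primary human breast tumour that had been separated by flow cytometry. In 14 arrays the cells carried CD44, an adhesion receptor for hyaluronan, on their surface and lacked CD24, a small mucin-like surface protein (CD44+/CD24- cells). In the other 15 arrays the cells were the remaining sorted cells of breast tumours, those with CD24 and those without either antigen (non-CD44+/CD24- cells). Before that step, cells that bound antibodies to the lineage antigens CD140B, CD31, CD18, CD16, CD10, CD3 or CD2 had been gated away. The labels call the arrays biological replicates, and which arrays share a tumour is not given in the sources used here, so p-values measure the spread between these samples. The median intensity per array lay between 7.35 and 10.9, between 1.94% and 5.76% of probe sets lay above an intensity of 100, and between 3.78% and 10.8% were at the lowest value of the table. None of 7 technical measures passed in a two-sided permutation test between the groups (adjusted p = 0.934 for each). The 3-prime to 5-prime ratio of the GAPDH and ACTB control probe sets, a measure of RNA degradation and amplification, was 4.45 ± 0.61 (log2, SD, n = 14) in CD44+/CD24- cells and 4.47 ± 0.61 (n = 15) in non-CD44+/CD24- cells (difference -0.02, permutation p = 0.918). This log2 ratio lay between 3.37 and 5.70 over all arrays, so 5-prime signal was weak in both groups. Probe sets far from the 3-prime end may therefore miss changes. The number of arrays limits the precision of every value.

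The comparison asks how gene expression in CD44+/CD24- cells sorted from breast tumours, whatever their cell type, differs from that in the other sorted cells. CD24 RNA was lower in CD44+/CD24- cells, at 6.22 ± 1.05 on the log2(intensity + 16) scale (SD, n = 14) against 9.35 ± 1.25 (n = 15), a difference of -3.13 (SE 0.41, adjusted p = 4.09e-05), and all 14 arrays lay below the mean of the other group. CD44 RNA was higher, at 9.92 ± 0.67 against 8.79 ± 1.16, a difference of 1.12 (SE 0.34, adjusted p = 0.0425), and 13 of 14 arrays lay above the mean of the other group. All 6 probe sets of CD24 were lower, by differences from -3.15 to -1.97. All 13 probe sets of CD44 had a difference above 0, from 0.01 to 1.12, and 4 of them had an unadjusted p under 0.05. The CD44 call stood close to the threshold: it was lost with the mean of all its probe sets (0.39, adjusted p = 0.107), with a pseudocount of 64 (1.01, adjusted p = 0.0506), with the replicate number as a fixed block (1.12, adjusted p = 0.0985) and on leaving out any of 17 of the 29 arrays. It was also lost within each of 2 sets of arrays that differed in the share of probe sets at the lowest value, with 1.31 (adjusted p = 0.101) in the 19-array set and 0.72 (adjusted p = 0.714) in the 10-array set, where CD24 kept its call at -2.76 and -3.83.

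Among all genes, several of immunoglobulins and mast cells were among the 10 largest increases in CD44+/CD24- cells, and KRT18, KRT19 and EPCAM, genes of epithelial cells, among the 10 largest decreases. The 10 largest increases were in IGHM, the heavy chain of immunoglobulin M (4.61, SE 0.59), IGLV1-44 (3.71), IGHG1 (3.68), IGLL3P (3.63), IGLC1 (3.61), CPA3, a carboxypeptidase of mast cell granules (3.58, SE 0.38), KIT, the receptor for stem cell factor (3.56), IGKC (3.54), GUSBP11 (3.51) and HDC, which makes histamine (3.25). The 10 largest decreases were in KRT18, a keratin of simple epithelia (-4.0, SE 0.41), SERPINA3 (-3.71), SFN (-3.44), KRT19 (-3.30), EFNA1 (-3.14), CD24, TM4SF1 (-3.07), EPCAM, an epithelial adhesion molecule (-3.0), S100A14 (-2.72) and MGP (-2.63). Immunoglobulin probe sets, and those of TPSAB1 and TPSB2, match near-identical sequences, so the values of single members are uncertain. Without _x_at and _s_at probe sets, which puts another probe set in their place, IGLV1-44 (0.08), IGHG1 (0.35), GUSBP11 (0.00656) and MGP (-0.30) did not pass. In all, 1448 of 19740 genes (7.34%) changed in limma's test at a Benjamini-Hochberg adjusted p under 0.05, 680 higher and 768 lower, and 423 of them by 2-fold or more (201 higher, 222 lower). With array weights 2375 genes changed, with the array set as a block 1655, within the 19-array set 427 and within the 10-array set 24, where fewer arrays entered each test.

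**Figure D1:**
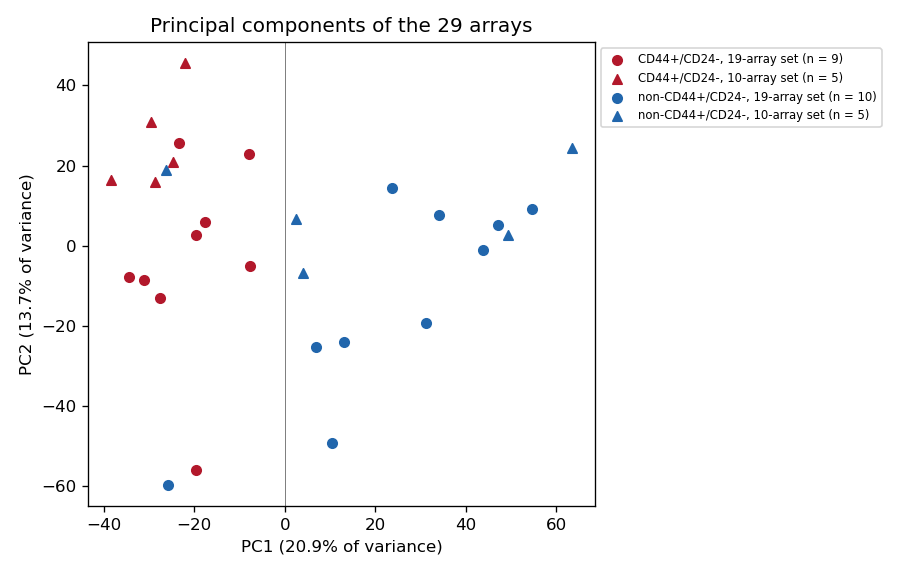
Each point is an array, placed by its scores on principal components 1 (horizontal, 20.9% of the variance) and 2 (vertical, 13.7%), in component units; colour gives the group and shape the array set. All 14 CD44+/CD24- arrays lie below 0 on component 1, as do 2 of the 15 non-CD44+/CD24- arrays.

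The arrays parted by group along the first principal component, with a mean score of -23.7 ± 8.90 (SD, n = 14) in CD44+/CD24- cells and 22.1 ± 27.5 (n = 15) in the other cells. The two-sided permutation p was 1e-05, the smallest that the permutations can give. The non-CD44+/CD24- arrays below 0 on it were replicates 6 and 14. In replicate 14 KRT18 was at 5.31 and EPCAM at 4.69, near the means of the CD44+/CD24- cells, while CD24 was at 10.21 and S100A8, a granulocyte protein, at 12.43. S100A8 was also high in non-CD44+/CD24- replicates 7, 12 and 13 (10.57, 10.69 and 9.90), where KRT18 was at 11.03, 9.59 and 10.65. Replicate 6 was the dimmest array (1.94% of probe sets above an intensity of 100), with KRT18 at 7.67 and EPCAM at 6.98, between the 2 group means, and HBB, a haemoglobin chain, at 12.51, while replicate 12, above 0 on this component, had HBB at 13.69. High HBB was not particular to the non-CD44+/CD24- arrays: CD44+/CD24- replicates 5, 6 and 7 had it at 10.04, 11.15 and 11.81.

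Genes of B lymphocytes and plasma cells rose together in CD44+/CD24- cells. All 14 measured members of the list were higher, both over all genes and adjusted over the list alone, with a median difference of 1.67 and a mean of 1.98. JCHAIN, which joins immunoglobulin units (3.09, adjusted p = 0.000111), POU2AF1, a B cell transcription coactivator (1.85, adjusted p = 0.000265), and CD79A, a chain of the B cell receptor (1.92, adjusted p = 0.000698), were among those with the smallest p-values beside IGHM. The list shifted up in camera (adjusted p = 3.51e-20, and adjusted p = 0.0145 with an estimated correlation). The difference of the list's mean was 1.93 within the 19-array set (exact permutation p = 7.58e-05) and 2.05 within the 10-array set (exact permutation p = 0.00794). MHC class II genes, which present antigen on B cells, macrophages and dendritic cells, rose in 6 of 8 members, 7 adjusted over the list alone, with HLA-DPA1 at 2.10, CD74 at 1.75 (not past the threshold with the mean of its probe sets), HLA-DRA at 1.51 and HLA-DMA at 1.04. Their shift up (adjusted p = 6.41e-07) was lost with an estimated correlation (adjusted p = 0.155 with an estimated correlation).

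Mast cell genes rose while granulocyte genes of the same list did not pass. Of 15 members 5 were higher, over all genes and adjusted over the list alone: CPA3 (3.58, adjusted p = 2.22e-06), TPSAB1 (2.73) and TPSB2 (2.94), the mast cell tryptases, KIT (3.56) and HDC (3.25). Adjusted over the list alone, 5 others were lower. S100A8 was at 5.24 against 7.09 on the log2 scale (difference -1.85, adjusted p = 0.104) and S100A9 had a difference of -1.94 (adjusted p = 0.0618). The list's median difference was -0.28, its mean 0.61 and its test direction up, so the median differed in sign from both, and the list did not pass over all arrays (adjusted p = 0.106, and adjusted p = 0.825 with an estimated correlation). The mean of these 5 genes, picked because they passed, differed by 3.13 within the 19-array set and 3.34 within the 10-array set.

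**Figure D2:**
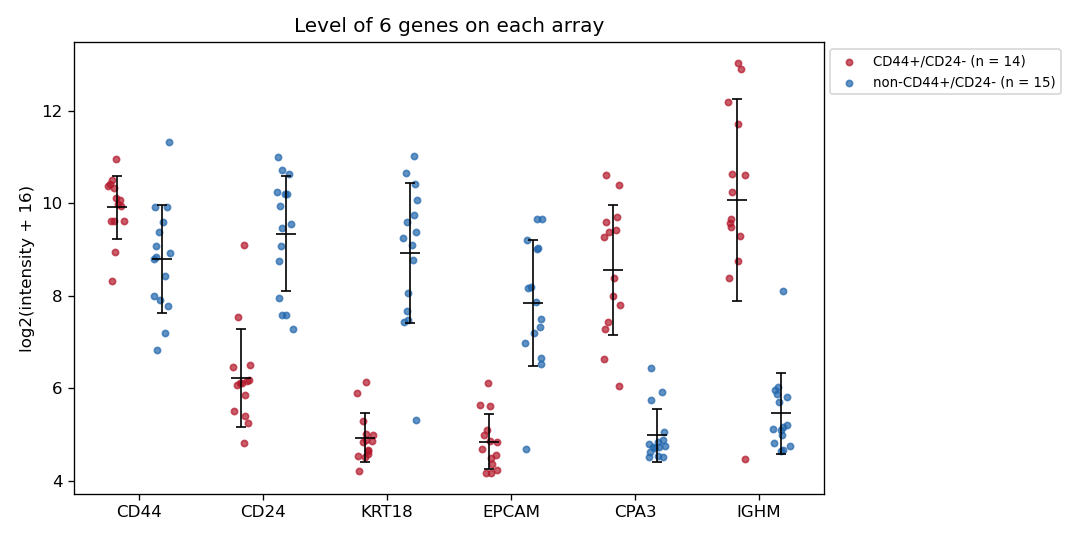
The vertical axis gives log2(intensity + 16) of 6 genes, each point an array, with black bars for mean and SD of the 14 CD44+/CD24- and 15 non-CD44+/CD24- arrays. CPA3 averages 8.57 against 4.99 and KRT18 4.93 against 8.93, while the groups overlap in CD44.

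Genes of luminal epithelium and of cell junctions fell in CD44+/CD24- cells. Of 21 luminal genes 10 were lower, 14 adjusted over the list alone, among them KRT18, KRT8 (-2.18), KRT19 (-3.30) and ELF3, an epithelial transcription factor (-2.09). Of 27 junction genes 20 were lower, 23 adjusted over the list alone, among them EPCAM, the claudins CLDN7 (-1.65) and CLDN4 (-2.12), and JUP, which links cadherins and desmosomes to the cytoskeleton (-2.10). No member of either list was higher. The luminal list shifted down with an adjusted p of 9.31e-12 and the junction list with 4.94e-22, and both calls held with an estimated correlation (adjusted p = 0.0383 with an estimated correlation for each). The luminal mean differed by -1.36 within the 19-array set (exact permutation p = 0.00013) and by -1.22 within the 10-array set (exact permutation p = 0.0714). Of 12 basal and myoepithelial genes 3 were lower, 4 adjusted over the list alone: SFN, KRT15 (-1.69) and LAMB3 (-1.07), while TRIM29 had a difference of -0.55 (adjusted p = 0.0755). That list's shift down (adjusted p = 0.000987) was lost with an estimated correlation (adjusted p = 0.196 with an estimated correlation).

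Regulators of epithelial to mesenchymal transition moved both ways. TCF4 (1.34, adjusted p = 0.000858), ZEB1 (1.05, adjusted p = 0.00134) and ZEB2 (0.94, adjusted p = 0.0123), transcription factors that repress epithelial genes and that lymphoid cells also express, rose, and SOX9 fell (-2.15, adjusted p = 0.00115). Adjusted over the list alone, 4 of the 12 were higher and 3 lower, and the list did not shift (adjusted p = 0.384). Of 29 mesenchymal and matrix genes VIM, an intermediate filament protein of mesenchymal and blood cells, was the only one that passed (1.90, adjusted p = 0.00315), also adjusted over the list alone. S100A4 had a difference of 0.49 (adjusted p = 0.300), TNC -0.61 and ACTA2 -0.80. The list did not pass in camera (adjusted p = 0.215, and adjusted p = 0.825 with an estimated correlation). At the preset correlation it shifted up within the 19-array set (0.0291) and without non-CD44+/CD24- replicate 4 (0.0181). The list's mean differed by 0.38 within the 19-array set (exact permutation p = 0.354), so the call there does not show a shift. None of 17 genes associated with stem cells passed, over all genes or adjusted over the list alone (list adjusted p = 0.384). ALDH1A3 had a difference of -0.79 (adjusted p = 0.0878), ALDH1A1 of 0.35 (adjusted p = 0.107) and MYC of -0.81 (adjusted p = 0.132).

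Markers of most other cell types did not pass. None of 18 fibroblast genes passed (list adjusted p = 0.250, and adjusted p = 0.825 with an estimated correlation), with POSTN at 0.53 and THY1 at -0.37. Without non-CD44+/CD24- replicate 4 the fibroblast list passed at camera's preset correlation (adjusted p = 0.0373). No member passed among 20 macrophage and monocyte genes (list adjusted p = 0.683), with FCER1G at 0.50. Of 20 T and NK cell genes IL7R, the interleukin 7 receptor (2.15, adjusted p = 0.00742), and KLRB1 (0.59, adjusted p = 0.0361) rose, the latter not with quantile normalization, with a pseudocount of 64 or on leaving out any of 12 arrays, while CD247 was at -0.34 (adjusted p = 0.0735). Adjusted over the list alone, 2 were higher and 1 lower (list adjusted p = 0.121). Among 16 endothelial genes FLT1, a receptor for vascular endothelial growth factors, rose (0.75, adjusted p = 0.0262), also adjusted over the list alone, and the list's median of -0.02 differed in sign from its mean of 0.03 and its test direction (adjusted p = 0.683). Without _x_at and _s_at probe sets FLT1 stood at -0.02 (adjusted p = 0.948). Of 12 pericyte and muscle genes NOTCH3 fell, also adjusted over the list alone (-0.71, adjusted p = 0.0104, list adjusted p = 0.583). No member passed among 9 red cell and platelet genes (list adjusted p = 0.413) or 11 adipocyte genes (list adjusted p = 0.899). None of 9 genes of the gated lineage antigens passed (list adjusted p = 0.676), and in these and the fibroblast and macrophage lists the count adjusted over the list alone was 0 too. The differences of the lineage antigen genes were -0.15 for ITGB2, the gene of CD18, and CD2, -0.10 for CD3E, -0.11 for CD3D, -0.06 for CD3G, 0.12 for PECAM1, 0.16 for PDGFRB, 0.02 for FCGR3B and 0.00 for MME. Several of these lists were near background. Group means were 5.06 and 5.09 for lineage antigens, 4.71 and 4.67 for endothelial and 4.79 and 4.77 for adipocyte genes. Array medians were 4.55 to 4.75 on the same scale. The lack of calls there says little about the cells present.

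Genes of energy metabolism, lipid synthesis, heat shock and the estrogen response were lower where they passed. Oxidative phosphorylation genes fell in 5 of 26 members, 10 adjusted over the list alone, including SDHC (-1.05) and COX5B (-0.74), and glycolysis and hypoxia genes in 3 of 23, 4 adjusted over the list alone, including ALDOA (-1.15). Cholesterol and lipid genes fell in 4 of 17, 5 adjusted over the list alone: DHCR7 (-1.11), SCD (-1.49), FASN (-0.81) and FDPS (-0.75). Heat shock genes fell in 2 of 10, 5 adjusted over the list alone (HSP90AB1 -1.10, HSPB1 -1.76), and estrogen response genes in 4 of 19, 7 adjusted over the list alone (FKBP4 -1.48, STC2 -2.02, TFF3 -0.97, CA12 -1.73). Of these, SDHC, COX5B, FKBP4, STC2 and CA12 did not pass without _x_at and _s_at probe sets, and leaving out 1 array ended the call of CA12 for 19 of 29 arrays, of HSPB1 for 16 and of TFF3 for 5. With the mean of all probe sets HSP90AB1 and CA12 did not pass, with a pseudocount of 64 HSPB1, TFF3 and CA12, and with quantile normalization HSPB1. Among 30 proliferation genes MCM5 was higher (1.04) and MCM4 (-0.94) and MCM2 (-0.63) lower, all 3 genes of the replication helicase, and adjusted over the list alone 1 was higher and 4 lower. MCM2 lost its call on leaving out any of 18 arrays, and MCM4 with the replicate block (adjusted p = 0.0520) and without _x_at and _s_at probe sets (-0.31). Of 20 apoptosis genes BMF, which promotes cell death (0.95), and BCL2, which blocks it (1.22), rose, and 4 were higher adjusted over the list alone. These 7 lists passed in camera, apoptosis shifted up and the others down. None kept the call: adjusted p = 0.577 with an estimated correlation for oxidative phosphorylation, 0.778 for glycolysis and hypoxia, 0.539 for cholesterol and lipid, 0.532 for heat shock and for estrogen response, 0.825 for proliferation and 0.323 for apoptosis.

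The remaining pathway lists did not pass over all 29 arrays. Immediate early genes fell in 3 of 26 members (IER2 -1.20, CCN1 -1.69, IER3 -1.68; list adjusted p = 0.0904), and their list passed, downward, within the 10-array set (adjusted p = 0.00275) and on leaving out any of 6 arrays. PTGS2, a prostaglandin synthase, rose (2.15) as the only one of 23 NF-kB and inflammation genes that passed (list adjusted p = 0.366). HERPUD1 (1.78) and EDEM1 (1.08), which serve the disposal of misfolded proteins, rose and TRIB3 fell (-1.30) among 18 unfolded protein genes (list adjusted p = 0.309), and HERPUD1 did not pass without _x_at and _s_at probe sets (0.04). RPL8 fell (-0.76) among 23 ribosomal protein genes (list adjusted p = 0.313), and no member passed among 23 interferon response genes (list adjusted p = 0.404). BAMBI (-1.52) and SMURF1 (-0.62) fell among 23 TGF-beta genes (list adjusted p = 0.515), and LRP6 (-0.65) and FZD7 (-0.53) among 24 Wnt genes (list adjusted p = 0.242). Leaving out 1 array ended the call of FZD7 for 13 arrays, of IER3 and TRIB3 for 12 each and of SMURF1 for 11, the replicate block ended those of FZD7, TRIB3 and SMURF1, and the mean of all probe sets those of LRP6 and JAG2. Among 20 Notch genes LFNG (1.51) and DTX1 (0.35) rose while JAG2 (-0.49) and NOTCH3 fell (list adjusted p = 0.683). None of 13 Hedgehog genes passed (list adjusted p = 0.873), and of 17 aldehyde dehydrogenase and transporter genes ALDH3B2 fell (-0.77, list adjusted p = 0.800). Both of these lists had a test direction up against a median and mean below 0. Adjusted over the list alone, 4 immediate early genes passed (1 higher), 1 NF-kB, 3 unfolded protein, 1 ribosomal, 0 interferon, 3 TGF-beta, 3 Wnt, 6 Notch (4 higher), 0 Hedgehog and 8 dehydrogenase and transporter genes (4 higher).

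**Figure D3:**
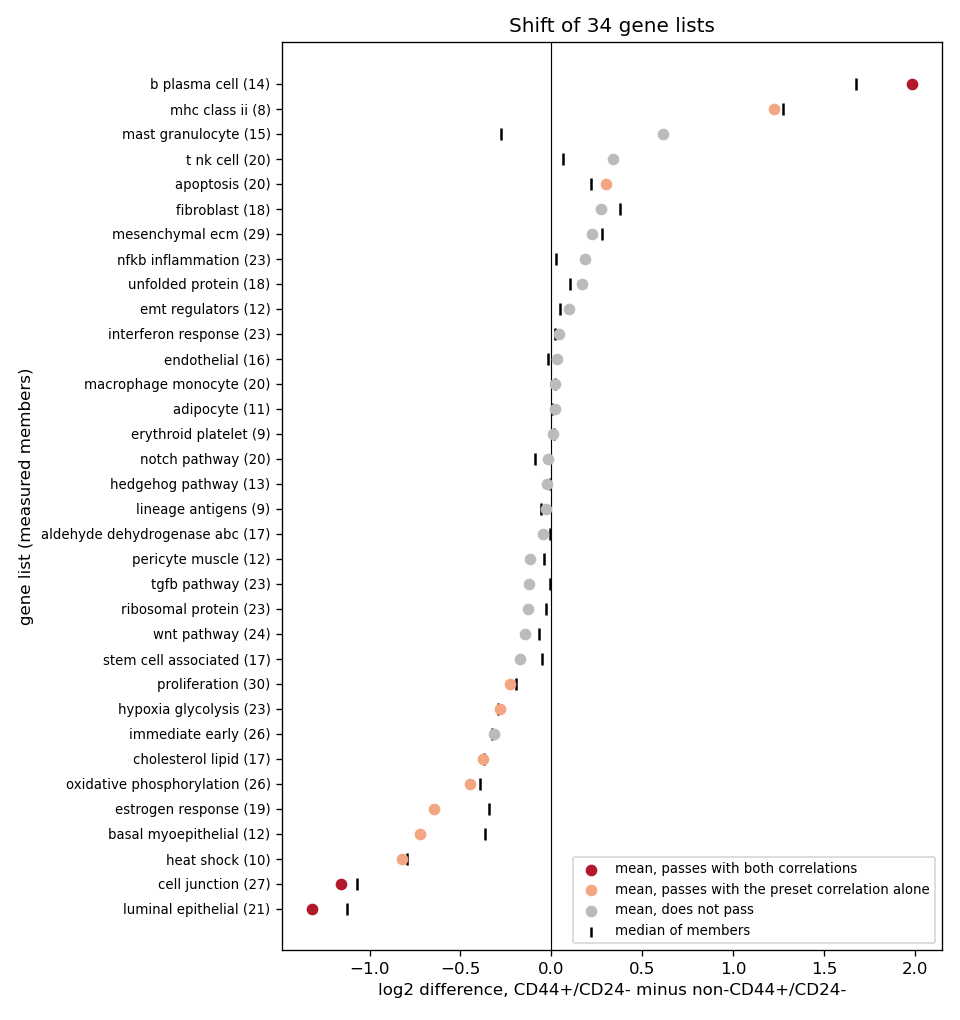
Each row is a gene list with its number of measured members, the dot its mean and the tick its median log2 difference (horizontal axis, CD44+/CD24- minus non-CD44+/CD24-). The B and plasma cell list (mean 1.98), the junction list (-1.16) and the luminal list (-1.32) passed with both correlations.

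In all, 12 of 34 lists shifted with camera's preset correlation, 3 up and 9 down, and 3 held with an estimated correlation: the B and plasma cell, luminal and junction lists. A count of 12 or more lists was also reached by other splits of the arrays, 28 of 100 with the real one included, so the count itself does not set the groups apart.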

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

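The fits by array set and the one without the 2 dimmest arrays were chosen after seeing the data. The numbers of changed, higher and lower genes stayed within 1.5 times 1448, 680 and 768 under 13 of 16 refits of all genes. With array weights they were 2375, 1045 and 1330, within the 19-array set 427, 240 and 187, and within the 10-array set 24, 20 and 4, where fewer arrays entered. Quantile normalization gave 1631 genes, 1365 of them shared with the 1448. Leaving out each array in turn gave 1209 to 1841 changed genes, 567 to 844 higher, 611 to 1079 lower, 10 to 14 lists, a CD24 difference of -3.35 to -3.01 and a CD44 difference of 0.98 to 1.30.

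CD24 kept its call wherever it had a value (without _x_at and _s_at probe sets it had none). CD44 was not past the threshold with a pseudocount of 64 (1.01), with the mean of its probe sets (0.39), with the replicate block (1.12, adjusted p = 0.0985), within the 19-array set (1.31) and within the 10-array set (0.72). It was also lost without CD44+/CD24- replicate 1, 2, 3, 4, 6, 10, 11, 12, 13 or 14 or non-CD44+/CD24- replicate 1, 2, 3, 6, 8, 10 or 11 (adjusted p up to 0.0689). The cause was not tested.

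The replicate block gave 1409 changed genes, 608 higher and 801 lower, and a random block 1737. Whether the numbers pair the samples was not settled: 6 of 14 same-numbered pairs correlated above 0.1 (range -0.25 to 0.30), and 5 of 29 arrays correlated best with their own number. No chance level was computed for these counts, and the correlation estimated for the random block was 0.066. Lists shifted fell from 12 to 3 with an estimated correlation. All refits used the preset correlation, and the estimated one was applied to the main fit alone, so the refits do not test that choice. The B and plasma cell, luminal and junction lists kept their call in every fit run. The glycolysis and hypoxia list (adjusted p from 0.00713 to 0.257) lost it with quantile normalization, without the lowest 40% of genes, without _x_at and _s_at probe sets, within the 10-array set, and without CD44+/CD24- replicate 6, 7, 9 or 14 or non-CD44+/CD24- replicate 1, 3, 7, 8, 14 or 15. The proliferation list (0.00236 to 0.0813) lost it without the lowest 40% of genes, without _x_at and _s_at probe sets, with the replicate block, within the 19-array set, and without non-CD44+/CD24- replicate 3, 8 or 15. The cholesterol and heat shock lists lost it without _x_at and _s_at probe sets, and the apoptosis and basal lists within the 10-array set. FLT1 (-0.023) and OVOL2 (0.050) changed sign without _x_at and _s_at probe sets, which puts another probe set in their place. Calls were gained by the immediate early list within the 10-array set and without CD44+/CD24- replicate 3 or 5 or non-CD44+/CD24- replicate 1, 2, 8 or 11, by the mast cell and granulocyte list without the lowest 40% of genes, within the 19-array set and without CD44+/CD24- replicate 9 or non-CD44+/CD24- replicate 14, by the mesenchymal and fibroblast lists as given above, and by the T and NK list without CD44+/CD24- replicate 3 or non-CD44+/CD24- replicate 12. Without _x_at and _s_at probe sets 11 of 139 named genes lost their call, as given above. Others lost it with a pseudocount of 64 (KLRB1, MCM2, HSPB1, TRIB3, TFF3, CA12, FZD7, SDC1, SLPI) or 1 (SMURF1), the mean of all probe sets (FLT1, CD74, HSP90AB1, CA12, LRP6, JAG2, CLDN18, NDUFV1), the replicate block (MCM4, TRIB3, CA12, SMURF1, FZD7, NDUFV1), quantile normalization (KLRB1, HSPB1), array weights (IER3) or without the 2 dimmest arrays (MCM2, CA12). Leaving out 1 array ended the calls of 9 of these genes, as given above, and that of NDUFV1 for 3 arrays. Of 184 named genes, 53 lost their call within the 19-array set and 103 within the 10-array set. The group difference of the 3-prime to 5-prime ratio was -0.07 with GAPDH alone (permutation p = 0.785) and 0.02 with ACTB alone (permutation p = 0.934). Signal limits dim genes, since at most 5.76% of probe sets per array exceeded an intensity of 100.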

Other observations

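All tests in this part were chosen after the results were seen, except those of other splits of the arrays and the gene and list values of the planned fits. The tests chosen afterwards include those of the 3-prime to 5-prime ratio, which took the place of a planned count of called genes that passed with the ratio as a covariate. A ratio balanced between the groups over all arrays could hardly have changed that count. The same holds for the 10 groups of genes below, of which 5 were of leukocytes and 5 of keratins, claudins, S100 proteins and other epithelial genes. Of 12 other mast cell genes 8 were higher and none lower (median 1.23), among them GATA2, a transcription factor of mast cell development (2.21), IL1RL1, the interleukin 33 receptor (1.89), HPGDS (1.40), and the granule proteases CMA1 (1.30) and CTSG (1.24), while FCER1A was at 0.21 (adjusted p = 0.0626). Of 14 other B lymphocyte genes 8 were higher and none lower (median 0.49), among them CCR7 (2.61), BANK1 (1.24), EBF1 (0.995) and CD27 (0.93). Of 7 plasma cell differentiation genes 4 were higher, including PIM2 (2.34) and IRF4 (0.66), and 1 was lower, SDC1 (-1.15, lost with a pseudocount of 64), which epithelial cells also express. Of 14 immunoglobulin genes, some of them named in the report, 9 were higher and none lower. Of 8 pan-leukocyte genes 3 were higher, including LAPTM5 (1.77) and CD53 (1.64), and PTPRC, the gene of CD45, was at 1.17 without passing (adjusted p = 0.169).

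Epithelial transcription factors and secretory genes outside the lists were lower. Of 10 such transcription factors 7 were lower and none higher, among them TFAP2C (-2.19), TFAP2A (-2.18), IRX3 (-1.98) and OVOL2 (-0.60, and 0.05 without _x_at and _s_at probe sets), while KLF5 was at -0.97 (adjusted p = 0.0510). Of 10 secretory epithelial genes 6 were lower, among them LTF (-2.44), AZGP1 (-2.43) and SLPI (-1.65, lost with a pseudocount of 64). Of 19 S100 genes 5 were lower, including S100P (-2.44) and S100A16 (-2.28). Of 20 claudins 4 were lower and 1, CLDN18, was higher (0.46, lost with the mean of its probe sets), and of 44 keratins 6 were lower. Fisher's exact test of called against other genes gave Benjamini-Hochberg adjusted p-values from 8.57e-07 to 0.0185 for 9 of the 10 groups and 0.135 for keratins, and since the groups were picked from these data these p-values are not independent evidence. No group's median changed sign with quantile normalization or with centring on array medians.

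B, plasma and mast cell genes were higher in CD44+/CD24- cells although an antibody to CD18, which most leukocytes carry, was part of the gate. The array set was argued against, since the B and plasma list differed by 2.05 within the 10-array set and 1.93 within the 19-array set. The 3-prime to 5-prime ratio was balanced over all arrays (difference -0.02), but differed by 0.19 within the 19-array set and -0.38 within the 10-array set. The part of the list's 1.98 that went with the ratio was 0.00544 (95% bootstrap interval -0.13 to 0.14), which restates the balance over all arrays. The difference of the ratio had opposite signs in the 2 sets while the list rose in both. In these arrays that argues against this measure of RNA quality as the cause, but only weakly. The ratio's differences within sets were not tested, and 0.19 was small against the SD of 0.58 in the 19-array set. The ratio rests on 2 control transcripts alone. A lower share of epithelial cells alone would raise the RNA of all other cells alike. The B and plasma list rose by 0.97 more than the 5 most abundant T and NK genes (95% bootstrap interval 0.32 to 1.63). The excess was 1.52 over those of fibroblasts (0.34 to 2.70) and 1.83 over those of macrophages (0.85 to 2.76). Within the 19-array set the exact permutation p was 0.0737 for T and NK genes and 0.0692 for macrophages. For fibroblasts it was 0.143 within the 10-array set. IL7R (2.15), GZMB (1.44) and CD69 (1.09) differed upward themselves, while PRF1 was at 0.41 and CCL5 at -0.03. The gate was aimed at these cell types, and genes such as C1QA (median intensity 20.1 in CD44+/CD24- cells) were dim, where differences are understated. A lower epithelial share therefore stays open. A candidate explanation is that B, plasma and mast cells were among the sorted CD44+/CD24- cells: within those 14 arrays 4 mast cell genes (1 tryptase) had a mean pairwise correlation of 0.754 and 11 B and plasma genes (no immunoglobulin chains) of 0.426, above the 95th percentiles of random sets matched on mean and SD, drawn from all genes (0.532 and 0.239) or from those called higher (0.640 and 0.372). IGKC stood at a median intensity of 2979, IGHM at 994, KIT at 680 and CPA3 at 460 in these cells. The 14 B and plasma genes had a mean correlation of -0.17 with the 5 mast cell genes over these arrays, so the 2 sets did not rise together. KIT is also known from breast epithelium, and RNA of sorted pools does not show which cells made it. Expression of these genes by tumour cells therefore stays open.

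Epithelial genes were lower in CD44+/CD24- cells. For RNA quality, the part of the luminal difference that went with the ratio was 0.000438 (95% bootstrap interval -0.11 to 0.07), which restates the balance over all arrays. The ratio differed by 0.19 and -0.38 within the 19-array and 10-array sets. The luminal mean was lower in both, which argues weakly against this ratio as the cause, since the ratio's differences within sets were not tested. The array set was spread nearly evenly over the groups (9 CD44+/CD24- and 10 other arrays, and 5 and 5). As a block it could therefore hardly move the luminal mean, which differed by -1.31 with it (95% interval -1.81 to -0.82) and -1.32 without. That value restates the balance, while 1655 genes changed instead of 1448. Within the 19-array set the luminal mean differed by -1.36 (exact permutation p = 0.00013), which argues against the array set as the whole cause there. The test chosen first asked for a p under 0.05 within each set and was missed in the 10-array set, where 5 arrays stood against 5 (-1.22, exact permutation p = 0.0714). In CD44+/CD24- cells KRT18, KRT8 and KRT19 stood at median intensities of 12.9, 6.79 and 10.2, against 591, 101 and 331 in the other cells. Their level in CD44+/CD24- cells was thus near the array medians. An epithelial to mesenchymal transition may contribute, but the mean of the mesenchymal and matrix list differed by 0.22 (95% bootstrap interval -0.42 to 0.86), which neither shows nor excludes it. A smaller share of epithelial cells stays open too, since low keratin RNA does not tell the 2 apart.

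TCF4, ZEB1, ZEB2 and VIM were higher in CD44+/CD24- cells (mean 1.31, 95% bootstrap interval 0.94 to 1.67), and RNA of other cells may account for it, although the gate held CD140B, which fibroblasts carry, and CD18. Over the 14 CD44+/CD24- arrays the mean of the 4 genes had r = 0.393 (permutation p = 0.164) and rho = 0.301 (permutation p = 0.295) with the B and plasma list, r = -0.02 without the 2 arrays farthest from its median and r = 0.584 over the 9 arrays of the 19-array set. Against fibroblasts, whose list differed by 0.28 (list adjusted p = 0.250, and 0.0373 without non-CD44+/CD24- replicate 4), the 4 genes rose by 1.03 more than that list (95% bootstrap interval 0.44 to 1.59), but most of its genes were dim, and the excess over its 5 most abundant genes (LUM, at a median intensity of 149 and a difference of 0.75, DCN at 0.66, CTSK, C1R, C1S) was 0.84 (-0.05 to 1.73, permutation p = 0.0867). In 6 relations of the 4 genes with the B and plasma, fibroblast and mast cell means no r passed after Benjamini-Hochberg adjustment, the nearest being fibroblasts in the non-CD44+/CD24- arrays (r = 0.650, adjusted p = 0.0509). By rank, rho in those arrays was 0.668 for fibroblasts (permutation p = 0.00775) and 0.668 for mast cells (permutation p = 0.00794), both unadjusted. In the CD44+/CD24- arrays fibroblasts gave r = 0.167 (permutation p = 0.567). Mast cells there gave r = 0.428 (permutation p = 0.127) and rho = 0.512 (permutation p = 0.0646). Neither source can be told apart from expression by the tumour cells, because no relation passed over 14 arrays and the excess over abundant fibroblast genes had an interval that reached below 0.

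Splits of the arrays argue against chance for the number of changed genes. Of 100 splits into 14 and 15, 1 split, the real one, gave as many as 1448, and the highest other count was 2. The same held for higher genes (680, 1 split, highest other 2) and lower genes (768, 1 split, highest other 1). With 100 splits the share cannot fall below 1 in 100, and the splits took no account of array set or of tumours that arrays may share. Chance cannot be excluded for the number of lists: 28 of the 100 splits gave 12 or more, and the highest other count was 19.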
